A study of Mus musculus with 8 samples.

How the data were processed

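Bone marrow cells from mice were grown on irradiated AFT024 feeder cells in long-term culture medium, alone or with deoxycholic acid at 35 µM for 1 week, and lineage-negative cells were sorted, per the labels' protocols. Libraries were made with the 10x Genomics Chromium 3′ kit, version 3.1, with 8000 cells targeted per sample, per the labels' protocols. Cell Ranger 6.0 is named in the submitters' processing notes; the genome build, the annotation and any filter on cells are not given in the sources used here. The deposited values are UMI counts per gene and cell, whole numbers with no normalization, for 17866 cells and 32285 genes, of which 11246 genes had no UMI in any cell. Every column name gave a group. The culture design also names lithocholic acid, which was not analysed here.

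The labels list 4 samples in each group, lettered a to d, but cell names carry only the group, so the letters could not be told apart. The sources used here do not say whether a to d are separate samples or index reads of 1 library; the 9346 and 8520 barcodes of the groups stand beside the 8000 cells targeted per sample. Each group was treated as 1 library and no test, p-value or standard error was computed; the edgeR and camera tests planned for the case of separate samples were not run. Only 25 barcodes occurred in both groups. Xist was at 0.151 and 0.153 CPM and Ddx3y at 26.0 and 25.5 CPM in the media control and deoxycholic acid libraries, so sex-linked genes did not separate them.

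Cells with at least 300 detected genes and at most 10% of UMIs from mitochondrially encoded genes were retained. Scrublet, run in each library through scanpy 1.11.5, marked under 0.5% of cells with its automatic threshold, so the cells with the highest 6% of scores were removed, which with ties came to 6.44% of media control and 6.72% of deoxycholic acid cells. Counts per 10000 were log-transformed, and 2000 highly variable genes, 30 principal components and 15 exact nearest neighbours gave a graph weighted by shared neighbours. Clusters of both libraries together came from Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with no integration. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

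Clusters were named from markers of 19 cell classes fixed before the data were examined; the rule that turned markers into names was not fixed then. A marker was raised when it had at least 20 CPM and a log2 fold of at least 0.5 over the other cells, with 10 CPM added to each side. A name needed 3 raised markers and at least as many markers among the 10 leading genes as any other class. A first version of this rule settled ties by the mean fold. After its names and class shares had been seen it was replaced by a version in which ties give no name and a neutrophil name is withheld where at least 3 leading genes are among Vcan, Mpeg1, Fn1, Tcf7l2, Ahnak and S100a4. The replacement left unnamed cluster 14 (2.26% of media control and 2.09% of deoxycholic acid cells; mature neutrophil-like before), cluster 16 (1.05% and 1.37%; conventional dendritic cell-like before) and cluster 18 (0.259% and 0.155%; erythroid-like before). The share ratios under the first version are given in the closing section.

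UMIs were summed over the cells of a library, or of a class with at least 100 cells per library, and divided by the total to give CPM. Ratios of deoxycholic acid over media control have exact intervals from the binomial distribution of the UMIs between the libraries, and sums and shares have exact Poisson and binomial 95% intervals. UMIs of 1 cell are not independent draws, so these intervals cover counting error only. A 0 in 1 library was set to a floor of 3 counts. The genes named were set before the data were examined: the 10 largest positive and 10 largest negative log2 ratios among genes with at least 20 CPM and 50 UMIs in the higher library, in all kept cells and in GMP-like cells; the 5 largest each way in other classes; the bile acid receptors, of which 1 is not reported here; and the 4 members of each list with the highest mean CPM. Other list members were named as well where the text describes a list, chosen after their values were seen. These were Hk2, Bnip3, Eno1 and Cdk1 in all kept cells, Cd14, Mpo, and Bnip3 in GMP-like cells. For 25 gene lists fixed in advance, members with at least 5 CPM in either library gave a median log2 ratio, set against 10000 random lists, each member replaced by 1 of the 100 genes nearest to it in mean CPM. Transcript length and GC content were taken by gene symbol from GENCODE vM21 (GRCm38), used for these properties and not for coordinates. A trend on either was taken to test nothing where it moved genes by a median of less than 0.05 on the log2 scale, a limit set after the correlations with both had been seen.

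The ratio and list computations were tested on simulated counts for all kept cells, drawn for 32285 genes with 200 genes changed by a fold of 2. The log2 ratio came within 0.2 of the simulated value for 100% of changed genes. The intervals held the simulated ratio for 94.7% of 4497 genes, and 5.00% of unchanged lists fell outside the 2.5 to 97.5 percentiles. These rates check the computation on simulated counts only. They do not give the coverage of the intervals or the error rate of the lists in the deposited counts. There, UMIs of a cell are not independent draws and genes of a list may vary together. Alternatives were other cell filters, no doublet removal, other resolutions, other gene sets for clustering, each library clustered on its own, other scalings and low-count limits, and thinned cells. Added after seeing the data were clustering without genes that differed between the libraries, the automatic Scrublet threshold, the first naming rule, basophil marker UMIs without clusters, list values less the trend on transcript length, basophil marker UMIs of cells thinned to 2000 UMIs, list values without basophil-like cells, list values as the mean over classes or without clusters led by Bnip3 or Ankrd37, and GMP-like list values under the other cell filters and clusters.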

Results

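Single-cell RNA sequencing was used to compare mouse whole bone marrow cells kept for 1 week on AFT024 cells, a stromal cell line from fetal liver that serves as a feeder layer, with or without deoxycholic acid. Deoxycholic acid is a secondary bile acid, made by gut bacteria from a primary bile acid, and was given at 35 µM. The series title names the vitamin D receptor and myelopoiesis, the formation of myeloid blood cells. Lineage-negative cells were sorted before capture, so the shares below describe cells that passed that gate. The labels list 4 samples per group, but the deposited counts carry only a group name for each cell. Whether these were separate cultures or libraries, or parts of 1 library, is not given in the sources used here. Each group was therefore treated as 1 library, and no test between the groups could be made. The media control held 9346 barcodes with 183462851 UMIs and a median of 18781 UMIs per barcode. The deoxycholic acid library held 8520 barcodes with 131341422 UMIs and a median of 14604.5. After filtering, 8479 and 7762 cells were kept, with median depths of 18801 and 14418 UMIs. All intervals are exact 95% intervals, limits from a count of 0 rest on 3 counts, and both cover counting error only; no difference below has a replicate check.

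Progenitors with primary granule enzymes and neutrophils were the largest named classes, while 33.3% of media control cells and 35.9% of deoxycholic acid cells lay in clusters left without a name. Granulocyte-monocyte progenitor-like (GMP-like) cells, in clusters 3 and 7, carried Elane (neutrophil elastase) at 7638 CPM against 1823 in the other cells, and Mpo (myeloperoxidase) at 1750 against 321. Immature neutrophil-like cells carried Ltf (lactoferrin) at 2845 CPM against 292 elsewhere and Camp (cathelicidin) at 18972 against 3949. Of their clusters, cluster 2 (1705 cells) lay near the mature class, with 9 mature and 7 immature neutrophil markers raised. Mature neutrophil-like cells carried Mmp9 (a secreted protease of neutrophil granules) at 422 CPM against 2.83 and Cxcr2 (a chemokine receptor) at 250 against 9.36. Basophil-like cells carried Prss34 and Mcpt8, proteases of basophil granules, at 3979 and 8299 CPM against 0.245 and 45.6. A further cluster, 10, was called monocyte-like from Ccr2 (63.7 CPM against 2.98) and Ms4a6c (56.0 against 5.36), and it also held Mpo at 1256 CPM. Cluster 17 had a raised set of stromal fibroblast markers but none of those markers among its leading genes, so it stayed unnamed. It had a median of only 3336 UMIs and made up 1.01% of media control cells and 0.825% of deoxycholic acid cells.

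The main neutrophil and progenitor classes had similar shares in both libraries, and the basophil-like share was lower with deoxycholic acid. Immature neutrophil-like cells made up 34.0% of media control cells (33.0 to 35.0) and 35.8% of deoxycholic acid cells (34.7 to 36.9). Mature neutrophil-like cells made up 6.65% (6.13 to 7.20) and 6.31% (5.78 to 6.88). GMP-like cells made up 18.4% (17.5 to 19.2) and 16.9% (16.1 to 17.8), a ratio of 0.921 (0.855 to 0.992), but at a Leiden resolution of 2 the ratio was 1.01 (0.940 to 1.08). Basophil-like cells were 150 of the media control cells, 1.77% (1.5 to 2.07), and 92 of the deoxycholic acid cells, 1.19% (0.957 to 1.45), a ratio of 0.670 (0.511 to 0.874), though 2 of the 10 leading genes of their cluster differed between the libraries inside it. With each library clustered on its own, the ratios were 0.582 for GMP-like, 0.764 for immature neutrophil-like, 1.21 for mature neutrophil-like and 0.450 for basophil-like cells. Of those basophil-like cells, 77.7% were basophil-like in the joint clusters. Names then fell on different sets of clusters in the libraries, so these ratios do not compare like sets of cells. A media control cluster of 995 cells with 7 immature neutrophil markers raised was named immature neutrophil-like. A deoxycholic acid cluster of 844 cells, also with 7 raised, stayed unnamed. The monocyte-like cluster held 5.91% and 3.96% of cells, but 4 of its 10 leading genes differed between the libraries inside it by a log2 ratio of at least 0.5. When cells were clustered without genes that differed, the basophil-like class held 97.1% of the basophil-like cells above, with a ratio of 0.681 (0.518 to 0.891). The monocyte-like name then fell on a largely different set of 340 cells, of which 40.3% were monocyte-like before, so no share of the first set is compared. Of the 808 cells first called monocyte-like, only 16.96% kept the name there. GMP-like clusters led by Mpo took 31.56% and 27.85% of them, and a cluster named erythroid-like took 22.03%. At resolution 2, with all genes, 84.16% kept the name. The monocyte-like name of these cells therefore depended on the genes used. Cluster 14, led by Csta2, Mmp8 and Vcan, met the marker rule for mature neutrophils but was left unnamed after its leading genes were seen; it held 2.26% and 2.09% of cells.

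**Figure D1:**
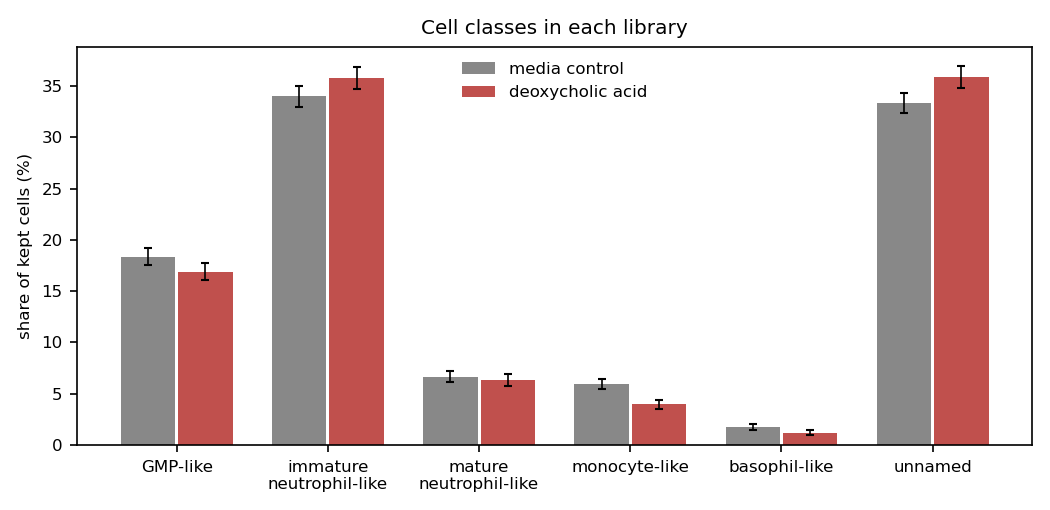
Share of kept cells (%) in each cell class for the media control and deoxycholic acid libraries, 1 library each; bars start at 0 and error bars are exact binomial 95% intervals. Basophil-like cells were 1.77% in the media control and 1.19% with deoxycholic acid, while mature neutrophil-like cells were 6.65% and 6.31%; the monocyte-like bars are not comparable, since leading genes of that cluster differed between the libraries.

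In all kept cells, the transcription factor gene Cebpb, which acts in granulocyte and macrophage formation, was lower with deoxycholic acid, at 121 CPM against 230 in the media control (log2 ratio -0.92, -0.95 to -0.89). Hk2, which encodes the hexokinase that starts glycolysis, was higher, at 129 CPM against 75.8 (log2 ratio 0.77). The immediate early gene Fosb was at 48.7 CPM against 24.9 (log2 ratio 0.97) and Klf10, a TGF-beta inducible transcription factor, at 36.1 against 19.2 (0.91). Among the 4670 genes with at least 20 CPM and 50 UMIs in the higher library, the central 95% of log2 ratios ran from -0.54 to 0.44 around a median of 0.04.

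The 10 largest positive ratios in all kept cells included 6 histone genes: Hist1h4h (log2 ratio 1.04), Hist1h2ai (1.02), Hist1h2ap (1.02), Hist1h2br (0.90), Hist2h2aa1 (0.87) and Hist1h3b (0.86). The others were Gm10076, with the largest ratio at 1276 CPM against 617 (1.05), Fosb, Dleu2 (0.92) and Klf10. Histone genes lie in families of near-identical copies, so reads can be split between members, and Hist1h2af went the other way (-1.20). The 10 largest negative ratios were led by Smim26, at 8.04 CPM against 26.8 (-1.74), and Mrps28, a mitochondrial ribosomal protein gene (-1.54). Washc3 (-1.38), Med31 (-1.36), Dynlt1f (-1.34), Unc50 (-1.32), Srsf9 (-1.28), Sdhd, a subunit of mitochondrial complex II (-1.26), and Churc1 (-1.20) followed. With no minimum on CPM and UMIs, none of the 20 stayed among the 20 largest ratios, which then came from genes of few UMIs.

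Several of these ratios had 1 direction in every cluster compared. In each of the 17 clusters with at least 50 cells per library, Cebpb was lower with deoxycholic acid, with log2 ratios from -2.35 to -0.73. The -2.35 came from the unnamed cluster 17, of 86 media control and 64 deoxycholic acid cells. The next lowest value was -1.25, in cluster 9. Gm10076 was higher in all 17 (0.93 to 1.20), as were Hk2 (0.30 to 1.03) and Klf10 (0.46 to 1.84, the highest also in cluster 17). Srsf9 (-1.61 to -0.87) and Sdhd (-1.60 to -0.82) were lower in all 17. Smim26 and Unc50 were lower in 16 of 17, and Hist2h2aa1 was higher in 16 of 17. Hist1h3b was higher in 13 of the 15 clusters with a value (-1.27 to 1.89), and Hist1h2af was lower in 14 of 16 (-1.69 to 0.46).

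**Figure D2:**
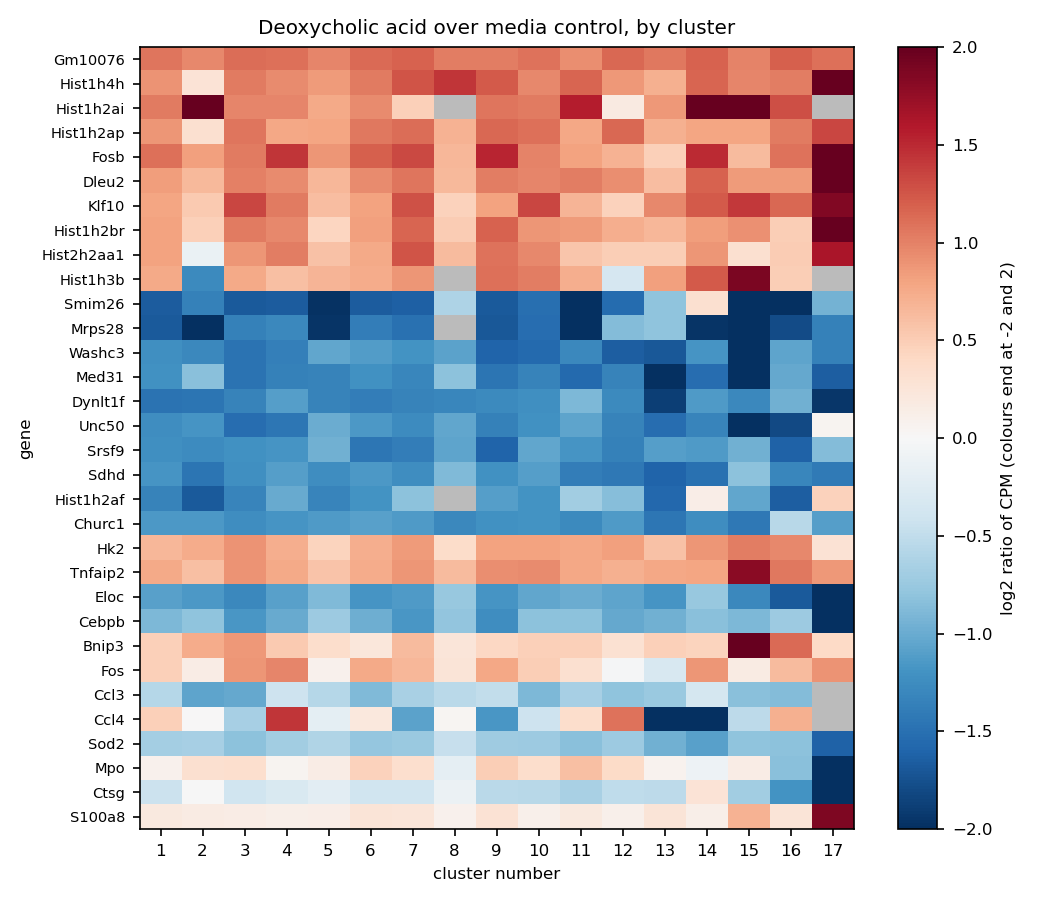
Log2 ratio of CPM, deoxycholic acid over media control, for named genes (rows) in clusters with at least 50 cells per library (columns); red is higher and blue lower with deoxycholic acid, colours end at -2 and 2, and grey marks no value. Cebpb lies below 0 in all 17 clusters and Gm10076 above 0 in all 17.

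Of the gene lists fixed in advance, glycolysis and hypoxia genes stood highest in all kept cells. There 15 of 16 measured members were higher with deoxycholic acid, with a median log2 ratio of 0.30 at the 100th percentile of 10000 random lists of like expression. Besides Hk2, Bnip3, a hypoxia-induced mitophagy receptor, was at 120 CPM against 75.3 (0.67), Eno1 at 571 against 429 (0.41) and Pkm at 726 against 623 (0.22), while Gapdh was at 2437 against 2570 (-0.08). Clusters led by the hypoxia-induced genes Bnip3 and Ankrd37, drawn without genes that differed, held 5.60% of media control and 7.65% of deoxycholic acid cells. Without such clusters (12 and 13 of the joint clusters) the list had a median of 0.24, and inside the 17 clusters its medians ran from 0.09 to 0.63. Bnip3 was higher in all 17, with a median of 0.48. G2 and M phase genes had a median of 0.17 (percentile 98.4), with 11 of 16 members higher: Mki67 was at 528 CPM against 415 (0.35) and Top2a at 443 against 360 (0.30), while Cdk1 was at 60.5 against 94.6 (-0.64). In the mean of the ratios within 4 classes (GMP-like, immature and mature neutrophil-like and monocyte-like), Mki67 was at -0.05 and Top2a at 0.15, and the G2 and M phase list reversed to -0.19 (percentile 0.01). With the mean over cells in place of sums, the G2 and M phase list lay inside the central 95% of random lists (percentile 94.6). The 16 measured S phase genes split 9 higher and 7 lower (median 0.01, percentile 43.4), with Pcna at 113 CPM against 169 (-0.58).

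Genes listed in advance as vitamin D receptor targets had a median log2 ratio of -0.41 (percentile 0.07), with 4 of 5 measured members lower. These were Cebpb, Spp1 (osteopontin; 29.3 CPM against 47.2, -0.69), Cd14 (5.90 against 7.85, -0.41) and Fbp1 (-0.04), while Cdkn1a was at 41.9 against 37.6 (0.16). With every detected member of that list included, the median was -0.04 (percentile 21.9). In the summed counts the 4 measured basophil and mast cell genes were lower (median -0.40, percentile 0.16), among them Prss34 at 14.9 CPM against 32.9 (-1.14), beside the smaller share of basophil-like cells. Inside basophil-like cells Prss34 was also lower, at 3104 CPM against 4374 (-0.49), while Mcpt8 (0.35), Cpa3 (0.21) and Hdc (0.31) were higher. In the mean of the ratios within 4 classes, which leaves out basophil-like cells, Prss34 was at -0.12 and Mcpt8 at 0.20. Inflammatory cytokines and chemokines had a median of -0.24 (percentile 0.32), with 6 of 8 lower, including Nfkbia, an inhibitor of NF-kappaB (286 against 360 CPM, -0.33). Without basophil-like cells the median was -0.14 and lay inside the central 95% of random lists (percentile 4.73). Ccl3, at 68.8 CPM in the media control (-0.93), was at 2040 against 3641 CPM in basophil-like cells and at 26.5 against 41.9 in the others (-0.66). Primary granule proteins had 7 of 8 members lower (median -0.23, percentile 2.18), including Ctsg (cathepsin G; 1468 against 2148, -0.55), and cytosolic ribosomal proteins 17 of 18 lower (median -0.23, percentile 0.56). Mpo, which is on the primary granule list, was higher in 13 of 17 clusters and lower in 4.

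Log2 ratios were higher for genes with longer transcripts (Spearman rho 0.422 across genes, which are not independent replicates), and the random lists were matched on expression alone. After this trend was taken out, the glycolysis and hypoxia (percentile 100), vitamin D receptor target (0.145), basophil and mast cell (0.17) and G2 and M phase (99.4) lists still lay outside the central 95% of random lists. Inflammatory cytokines and chemokines (9.52), primary granule proteins (8.56) and cytosolic ribosomal proteins (8.90) then lay inside it, and the unfolded protein response list moved outside (99.7).

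Lists were also computed from the mean of the ratios within the 4 classes, which weights each class alike and leaves out basophil-like and unnamed cells. The monocyte-like class is among the 4, although 4 of its 10 leading genes differed between the libraries inside its cluster. Its name also did not hold for most of its cells when clustered without genes that differed. The glycolysis and hypoxia (median 0.21, percentile 100), vitamin D receptor target (-0.47, 0.01), basophil and mast cell (-0.19, 2.20) and inflammatory (-0.25, 0.16) lists kept their direction and lay outside the central 95% of random lists. Random lists stayed matched on CPM in all kept cells. Outside basophil-like cells Prss34 had only 41 UMIs in the media control and 28 with deoxycholic acid. The percentile of the basophil and mast cell list therefore decides nothing here. Primary granule proteins (-0.10, 14.4) and cytosolic ribosomal proteins (-0.11, 11.9) lay inside it, as did primary granule proteins without clusters 12 and 13 (-0.22, 2.67). Secondary and tertiary granule proteins (-0.18, 0.725), S phase genes (-0.13, 0.53), the unfolded protein response (0.16, 98.4) and immediate early and heat shock genes (0.27, 100) lay outside it. The medians of myeloid transcription factors (-0.03) and interferon response (-0.09) lay below 0.

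**Figure D3:**
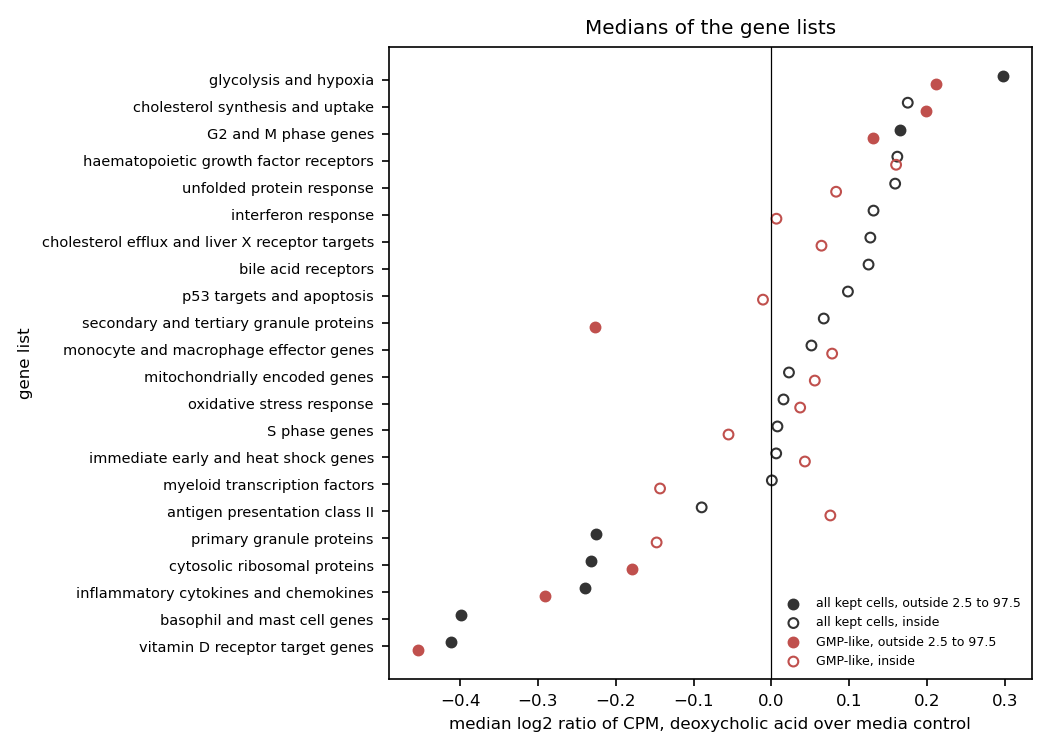
Median log2 ratio of CPM, deoxycholic acid over media control, of each gene list with at least 3 measured members, in all kept cells and in GMP-like cells; filled points lie outside the central 95% of 10000 random lists matched on mean expression. Glycolysis and hypoxia genes lie at 0.30 in all kept cells and 0.21 in GMP-like cells, and vitamin D receptor target genes at -0.41 and -0.45.

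The other lists lay inside the central 95% of random lists in all kept cells. Myeloid transcription factors had 6 of 11 members higher (median 0.00, and -0.09 without basophil-like cells); Cebpe was at 306 CPM against 302 (0.02) and Spi1 at 262 in both, and with DESeq2 size factors both ratios lay below 0. All 8 measured growth factor receptors were higher (median 0.16, percentile 90.6), including Csf2rb, the shared beta chain of the GM-CSF receptor, at 96.1 against 77.1 (0.32). Secondary and tertiary granule proteins had a median of 0.07; S100a8 was at 81347 CPM against 67689 (0.27) and S100a9, whose product pairs with that of S100a8, at 70410 against 81812 (-0.22), and in the mean of the ratios within 4 classes they were at 0.14 and -0.52. Medians were 0.05 for monocyte and macrophage effector genes, -0.09 for class II antigen presentation, 0.13 for interferon response (0.30, percentile 99.9, with every detected member), 0.16 for the unfolded protein response and 0.18 for cholesterol synthesis and uptake. They were 0.13 for cholesterol efflux and liver X receptor targets, 0.02 for oxidative stress response, 0.10 for p53 targets and apoptosis, 0.01 for immediate early and heat shock genes (0.18, percentile 97.9, without basophil-like cells) and 0.02 for mitochondrially encoded genes. Fewer than 3 members of the other lineage transcription factor, stromal matrix and haemoglobin lists were measured, so they have no median. Among their genes, Fli1 was at 72.2 CPM against 66.9, Fn1 (fibronectin) at 53.9 against 42.6 and Hbb-bt (a beta globin) at 2.90 against 3.53.

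In GMP-like cells, 1556 from the media control and 1312 with deoxycholic acid, 8 of the 10 genes with the largest positive ratios and 9 of the 10 with the largest negative ratios were also among those of all kept cells. Cebpb was at 81.3 CPM against 182 (log2 ratio -1.16, -1.24 to -1.09). Klf10 had the largest positive ratio, at 32.8 CPM against 13.2 (1.31), followed by Fosb (1.15), Gm10076 (1.14) and Hist1h2ap (1.13), with Hk2 at 155 against 84.1 (0.89) and Tnfaip2, a TNF-induced gene, at 203 against 110 (0.88). Fos and Jun, which form the AP-1 transcription factor, were at 142 against 80.6 (0.82) and 415 against 246 (0.76). Kit, the stem cell factor receptor, was at 51.7 against 34.3 (0.59). The largest negative ratios were those of Smim26 (-1.67), Unc50 (-1.42), Med31 (-1.41), Mrps28 (-1.41), Washc3 (-1.36), Dynlt1f (-1.33), Srsf9 (-1.27), Sdhd (-1.24), Eloc (-1.23) and Hist1h2af (-1.22). When each library was clustered on its own, 10 of the 20 genes stayed among the largest ratios.

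Glycolysis and hypoxia genes were again high in GMP-like cells, with 14 of 16 higher (median 0.21, percentile 99.8, but 0.06 and 78.1 with each library clustered on its own), and Bnip3 was at 72.8 CPM against 41.9 (0.80). Cholesterol synthesis and uptake genes had 12 of 15 higher (median 0.20, percentile 98.7, but 0.07 and 77.0 with a looser cell filter of at least 200 genes and at most 20% mitochondrial UMIs), with Srebf2, a regulator of that pathway, at 70.5 against 57.7 (0.29) and Fdps at 675 against 875 (-0.37). G2 and M phase genes had a median of 0.13 (percentile 98.3), but lay inside the central 95% of random lists with the mean over cells (92.4), the looser filter (61.8), a stricter filter of at least 1000 genes and at most 5% mitochondrial UMIs (95.1) and separate clustering (94.3). Vitamin D receptor target genes had 3 of 4 lower (median -0.45, percentile 0.19). Secondary and tertiary granule proteins had 9 of 12 lower (median -0.23, percentile 0.58), but lay inside the central 95% of random lists with the stricter filter (-0.09, 21.8), without doublet removal (-0.14, 4.19) and at resolution 2 (-0.08, 20.6). Their RNA was also found in basophil-like cells, which should lack it: Ngp was at 1087 CPM in the media control and 2660 with deoxycholic acid there, at median depths of 5798 and 4281 UMIs, beside 2738 and 2425 in GMP-like cells at 23818.5 and 17889 (log2 ratio -0.18, and -1.35 with separate clustering). Inflammatory cytokines and chemokines had 4 of 7 lower (median -0.29, percentile 0.31, but -0.14 and 7.82 with the looser filter), though Cxcl2 was at 114 against 81.8 (0.48, and 0.90 with the stricter filter), and cytosolic ribosomal proteins had 16 of 18 lower (median -0.18, percentile 1.11). Primary granule proteins (median -0.15, percentile 7.92), which define this class, lay inside the central 95% of random lists. Mpo was their 1 higher member, at 2001 CPM against 1585 (0.34). After the trend on transcript length was taken out, the cholesterol synthesis (percentile 95.8) and ribosomal protein (4.08) lists lay inside the central 95% of random lists, and the immediate early and heat shock list moved outside (99.1), as it did with every detected member included (median 0.67, percentile 100).

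In immature neutrophil-like cells, all 5 genes named in each direction were also among those of all kept cells. They had Gm10076 (1.01), Hist1h2ai (1.00), Fosb (0.98), Hist1h4h (0.91) and Hist1h2ap (0.87) highest, and Dynlt1f (-1.37), Hist1h2af (-1.29), Sdhd (-1.26), Churc1 (-1.17) and Srsf9 (-1.15) lowest. In mature neutrophil-like cells 1 of 5 higher and 2 of 5 lower genes were shared with all kept cells: Vwa5a (1.42), Stfa1, a cysteine protease inhibitor (1.29), and Serpinb2 (1.12) were highest with Gm10076 (1.02) and Scaf4 (1.01). Their lowest were Retnla (-1.97), Rgs14 (-1.32), Dynlt1f (-1.30), Churc1 (-1.30) and Pdcl3 (-1.25); several of these rest on few UMIs, as for Retnla at 6.53 CPM against 25.5 (interval of the log2 ratio -2.81 to -1.21). Monocyte-like cells had Klf10 (1.34), Hist1h2ap (1.10), Gm10076 (1.08), Egr1 (1.06) and Hist1h3b (1.03) highest and Camp (-1.80), Washc3 (-1.55), Rpl9-ps6 (-1.55), Mrps28 (-1.53) and Smim26 (-1.50) lowest. These monocyte-like ratios may compare unlike cells, since 4 of the 10 leading genes of that cluster differed between the libraries inside it. Most cells of that cluster were named GMP-like or erythroid-like when clustered without genes that differed. Camp is a gene that marked the immature neutrophil-like class.

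Vdr, the vitamin D receptor gene, was barely detected in either library. It had 46 UMIs in 8479 media control cells, 0.277 CPM (0.203 to 0.370), and 40 UMIs in 7762 deoxycholic acid cells, 0.340 CPM (0.243 to 0.463). A Vdr UMI was found in 0.507% of media control cells (0.367 to 0.683) and 0.425% of deoxycholic acid cells (0.293 to 0.597), at median depths of 18801 and 14418 UMIs. After each cell was thinned to 9958 UMIs, which left out 1883 and 2177 shallower cells, the shares were 0.227% (0.127 to 0.375) and 0.143% (0.0619 to 0.282). In GMP-like cells, 4 of 1556 and 2 of 1312 cells had a Vdr UMI. The share was 3.19% (1.84 to 5.13) and 2.61% (1.13 to 5.07) in monocyte-like cells, at median depths of 29798 and 21137. Thinned to 9958 UMIs, 3 of 485 and 2 of 296 monocyte-like cells had a Vdr UMI. These were 0.619% (0.128 to 1.80) and 0.676% (0.0819 to 2.42). Since most monocyte-like cells were named otherwise when clustered without genes that differed, these shares are not a measure for monocytes. Among basophil-like cells 0 of 150 and 0 of 92 had one, at median depths of 5798 and 4281 UMIs. Those counts of 0 allow shares of cells with a UMI of up to 2.00% and 3.26% (3 counts over the cells), and exact intervals reach 2.43% and 3.93%. In immature neutrophil-like cells 1 of 2882 and 2 of 2777 cells had a UMI. In the unnamed cluster 17 there were 5 and 4 UMIs of Vdr in 86 and 64 cells, at median depths of 4021.5 and 2810. They came from 5 cells and 1 cell, and gave 7.73 CPM (2.51 to 18.0) and 12.8 CPM (3.48 to 32.7). A difference in Vdr between the libraries was not detectable at this depth.

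The list named for bile acid receptors also holds related nuclear receptors, such as Nr1h2 and Nr1h3, and partners. Of its other genes, Rxrb (27.5 CPM with deoxycholic acid against 25.2), Nr1h2 (21.8 against 20.2) and S1pr2 (5.53 against 4.97) reached 5 CPM. All 3 were higher, and the list had a median log2 ratio of 0.12 (percentile 64.0). Rxra was at 2.00 against 1.54 CPM (log2 ratio 0.37, and -0.12 in the mean of the ratios within 4 classes), Nr1i3 at 0.926 against 0.573 and Nr1h3 at 0.960 against 0.814. Gpbar1, the membrane bile acid receptor, had 5 UMIs with deoxycholic acid and 3 in the media control. Nr1h4, the farnesoid X receptor, had 1 UMI and 0 UMIs. Nr1i2 had none in either library, which allows up to 0.0255 CPM with deoxycholic acid and 0.0181 in the media control.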

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

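Clustering without genes that differed between the libraries, the automatic Scrublet threshold, the first naming rule, the marker UMIs (thinned ones too), the length trend, the lists without basophil-like cells, without clusters led by Bnip3 or Ankrd37 and as the mean over classes, and the GMP-like lists under other filters and clusters were chosen after seeing the data. No paired analysis was possible because the letters a to d are absent from the cell names, and whether they are separate samples is not given in the sources used here, so the replicate block, the leave-one-out fits and the DESeq2 Wald test were not run. The GMP-like share ratio, 0.921, reversed to 1.01 at resolution 2, where the class took in further cells and 86.5% of it had been GMP-like before. The monocyte-like ratio, 0.669, reversed to 1.19 with at least 1000 genes and at most 5% mitochondrial UMIs because the name moved to other cells: 7.11% of that class had been monocyte-like, and the former cells had a ratio of 0.665. With each group clustered on its own the ratios moved to 0.582 (GMP-like), 0.764 (immature neutrophil-like), 1.21 (mature neutrophil-like), 0.956 (monocyte-like) and 0.450 (basophil-like), with names given to different sets of clusters. The monocyte-like ratio was 0.904 when clustered without differing genes, where 40.3% of the class had been monocyte-like. Under the first naming rule, which was replaced after its result was seen, the mature neutrophil-like ratio was 0.942 against 0.949, and the GMP-like, immature neutrophil-like, monocyte-like and basophil-like ratios did not change. The basophil-like ratio lay below 1 in every alternative run. Without a limit on low counts, the central 95% of log2 ratios widened to -1.38 to 1.20 in all kept cells and -1.20 to 1.19 in GMP-like cells, and 0 of the 20 named genes stayed among the largest, by the construction of that setting. With each group clustered on its own 10 of the 20 did so in GMP-like cells. Zfpm1 (0.25) and Ifi27l2a (-0.13) in all kept cells changed sign in the mean over classes, and Cpa3 in GMP-like cells (0.52) with at least 1000 genes and at most 5% mitochondrial UMIs. The G2 and M phase list in all kept cells, 0.17, reversed to -0.19 in the mean over classes, and the cause was not tested. Thinning lowered the share of cells with a Vdr UMI to 0.227% and 0.143%, as fewer UMIs must. Of 134 values of the main results under alternatives, 117 stayed within their limits. Of 2147 values of named genes, 1656 stayed inside the counting interval and 488 moved out of it without a reversal as defined next; 104 in all had the other sign, 35 of them for genes whose interval left out 0. A reversal was counted only for those of the 35 with a log2 ratio of at least 0.5, the 3 named above. Of 619 values for genes of that size, 613 kept their sign, and the 3 further changes were of Hbb-bt and Col1a1 in GMP-like cells, whose intervals held 0. Of 333 list medians, 263 kept their sign and side of the random lists.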

Other observations

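The tests of class shares, of the sign in each class, of length by direction and of basophil markers without Mcpt8 and in thinned cells, and the clusters drawn without differing genes, were chosen after the results were seen. Clusters led by hypoxia-induced genes held a larger share of cells with deoxycholic acid. Clusters 12 and 13 were led by Bnip3, Ankrd37 and Selenbp1. Since Bnip3 itself differed between the libraries, their sizes were taken from clusters drawn without genes that differed by a log2 ratio of at least 0.5. Smaller differences stayed in, and the glycolysis and hypoxia list was higher inside all 17 clusters (medians 0.09 to 0.63). A shift of these genes in all cells could move cells into such clusters, which was not tested. There, the 2 clusters led by these genes held 5.60% of media control cells (5.12 to 6.11) and 7.65% of deoxycholic acid cells (7.07 to 8.27), a ratio of 1.37 (1.21 to 1.54).

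Some genes whose products work or are made together moved apart. The mitochondrial genome is transcribed as long precursors, yet in all kept cells mt-Co1 was at 5027 CPM with deoxycholic acid against 4248 (log2 ratio 0.24) and mt-Co2 at 2809 against 3357 (-0.26). RNA of neutrophil genes was also found in cells that are not neutrophils: in cluster 17, S100a8 was at 4577 CPM in the media control and 16689 with deoxycholic acid, and in basophil-like cells at 6691 and 10860. S100a9 was at 5399 and 14335 in cluster 17 and at 8845 and 8834 in basophil-like cells, and Mpo was at 176 and 25.6 in cluster 17 and at 186 and 206 in basophil-like cells.

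For genes with a log2 ratio of 0.5 or more in either direction in all kept cells, weighed first, the GC content of the last 500 bases gave no trend to remove (rho -0.007, median shift of a gene 0.013), so the 99.8% of their median absolute log2 ratio left after it tests nothing. A trend on transcript length, which moved genes by a median of 0.072, left 98.7% (90.4% for the lower and 107% for the higher genes). The medians of its length bins ran only from -0.18 to 0.18. For genes chosen at 0.5 or more, the fall to 50% predicted for a cause could therefore not occur. These percentages show only that the common trend was smaller than these ratios. Length stays open for the lower genes, which had a median length of 1588 bases against 3135 for all genes. They shared 91 bases of their 3′ end with another gene more often than the other genes did (13.5% against 5.94%), which leaves read sharing open for those genes and argues against it for most. For the genes of either direction, the mean of within-class ratios kept 92.8% of the size of the ratios. This argues against the shares of these 4 classes as the main cause. The monocyte-like class is among the 4, although 4 of its 10 leading genes differed between the libraries inside its cluster. Most of its cells also lost the monocyte-like name when clustered without genes that differed. A mean without that class was not computed, and shifts within a class were not covered. The same sign in all 4 classes was found for 87.4% of the genes of either direction. An action of deoxycholic acid on every class and a difference between 2 single libraries both give this, so these cannot be told apart.

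Lower Cebpb was weighed next. After trends on GC content and length its log2 ratio less the median of all genes went from -0.96 to -0.77. The medians of the length bins ran only from -0.18 to 0.18, and the GC trend moved genes by a median of 0.013. The rise predicted for a cause could therefore not occur, and nothing about those properties is decided. The mean of the within-class ratios of Cebpb was -0.90, so class shares do not account for the whole of its lower value. A response to deoxycholic acid is one hypothesis, consistent with these values, but a difference between the 2 libraries stays open and was not testable.

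For the smaller basophil-like share, weighed last, the ratio by at least 3 UMIs over the basophil markers, with no clusters, was 0.842 (0.761 to 0.932) in kept cells and 0.858 (0.780 to 0.944) in all deposited barcodes, which did not decide between the predictions set in advance. That measure took in 10.5% of media control cells, since Mcpt8 was also found outside basophil-like cells. Without Mcpt8 the ratio was 0.643 (0.499 to 0.825), but depth differed between the libraries and Prss34 was lower per basophil-like cell. With each cell thinned to 2000 UMIs, leaving out 126 and 112 shallower cells, and with neither Mcpt8 nor Prss34, it was 0.633 (0.471 to 0.847), which argues against the drawing of clusters as the cause. Differences between single cultures or sorts may give such a ratio, and no value here bears on that.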
